A study of Homo sapiens with 4 samples.

How the data were processed

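RNA from the colorectal cancer lines DLD1 and HT29 was profiled on 4 single-colour arrays, 1 for each line and medium. Per the labels' protocols, cells were moved from complete medium to medium without glucose and glutamine, with 10% dialysed fetal bovine serum, to which 10 mM glucose or 2 mM glutamine was added. By the sample titles, the medium with glucose held both, and the other held glutamine alone. RNA was taken after 24 h with an RNeasy kit, amplified as amino-allyl RNA and coupled to Cy5. Groups were taken from the sample titles and characteristics, and no label states whether the cultures were repeated.

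The deposited scanner files hold, per the file headers, the median intensity of each spot and of the area around it at 635 nm, joined from 3 scanner gains, with no background subtracted. The image software is not given in the sources used here. The deposited value table holds intensity on a linear scale. Set against the scanner values, each column of it was a straight line of the array's spot median (r above 0.999), with about the level of the blank spots subtracted and a median of 25.0 on each array. Its empty cells belonged to spots dimmer than every listed spot of the array, except 1 flagged spot in DLD1 without glucose. Its scale, centring and direction are thereby known, although no source used here states how it was made. Each array had 27456 spots, of which 2680 were blank and 24460 were probes. The median probe signal was 54.8 and 54.6 in DLD1 with and without glucose and 57.9 and 53.1 in HT29, against blank medians of 34.4, 34.8, 35.6 and 35.4. The 4 arrays are few, and their number limits the precision. No slide or scan date was used.

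Spot medians were corrected with the normexp method (offset 50) over all spots and quantile normalized with limma 3.58.1 in R 4.3.3. The local background was not used, because it followed the spot signal (r of the logs 0.910 to 0.968). An offset of 50 shrinks the changes of dim genes. Control spots and 1 probe with a spot flag were then left out. A probe was above background where it exceeded the 95th percentile of the blank spots. Gene symbols came from the platform annotation. Of 24460 probes, 20236 had 1 symbol, 0 had several and 4224 were not named. Older symbols (2490) were updated through NCBI RefSeq synonyms where the newer one was not on the array, leaving 17605 genes. A gene's value was the mean of its probes above background on at least 1 array. For 1742 genes with 2 probes above background on all arrays, the changes from the 2 probes had r = 0.708 in DLD1 and 0.738 in HT29, so single probes can disagree. Where a group was below background, a fold was given as a lower limit against the dimmest probe above background on that array, computed from normalized log2 values.

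Within a line, genes were counted at a 2-fold minimum with no test. The mean effect of the medium was tested with limma (line as a block), and the line effect with the medium as a block, each with Benjamini-Hochberg adjustment at 0.05. The lines themselves pair the arrays. The p-values measure the spread between 2 lines only. Adjustment over a list alone was repeated for each list, with no correction across lists. Over all genes the smallest limma adjusted p for the medium was 0.302. Lists were read by the median change and its percentile among 10000 random lists of equal size matched on expression in 10 bins, and by limma's camera with a correlation of 0.01 or an estimated one. With an estimated correlation, camera's p-values rest on the 1 residual degree of freedom of the fit and have little power. Of 36 lists, 35 had at least 5 measured genes. Camera and the mean of the 2 medians differed in sign for fatty acid oxidation, enterocyte and goblet differentiation, and mesenchymal markers, none of which had a camera adjusted p below 0.05. Figures were drawn with matplotlib.

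The genes named were set by a rule before the data were examined: the 12 highest and 12 lowest by the smaller of the changes in the 2 lines; for each line the 5 highest and 5 lowest among 2-fold changes with under 0.5 log2, or the opposite sign, in the other line; the 8 highest each way between the lines in both media; up to 4 members of each list by mean change; and GLUD1, SLC25A13 and the measured glutaminolysis genes. Of the line comparison, 1 gene is not reported here. Further list members are named as examples. They were chosen after their values were seen.

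The procedure was tested on simulated data for the medium effect with 15616 genes, the spread of each gene drawn from the residuals of the real fit. The 2-fold count in both lines found 0%, 34%, 98% and 98% of genes planted at 1.5, 2, 4 and 8-fold, and limma's adjusted p 0% at each size. Of unchanged genes 44 were counted, 6.33% had a limma p below 0.05, and 1 of 20 unchanged lists stood apart in both lines. The simulated genes varied independently and with equal spread in both lines. The rate for lists therefore does not carry over to real lists whose genes change together.

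Alternatives planned beforehand were no background correction, median scaling, cyclic loess, the deposited value table, no filter or a stricter filter on dim probes, fold minimums of 1.5 and 3, no block, an intensity trend in limma, and leaving out a line or a medium. An offset of 5 and normexp on the signal minus the local background were added after seeing the data. The medians of 3 lists relative to the positive control spots were also computed then, on values not scaled between arrays.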

Results

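Gene expression was measured in DLD1 and HT29, established human colorectal adenocarcinoma lines, after 24 h in medium with 10 mM glucose and 2 mM glutamine or in medium with 2 mM glutamine and no glucose, in both cases with 10% dialysed serum. Each line and medium had 1 single-colour (Cy5) oligonucleotide array, 4 arrays in all, so a difference within a line has no replicate check and carries no p-value. The 2 lines were the only repeats of the change of medium. Between 85.5% and 87.0% of the 24460 probes lay above the blank spots on each array, and 15616 genes with a symbol were above background on at least 1 array of each line. The number of arrays limits the precision of every value below. Changes are log2 values without over with glucose, positive where expression was higher without glucose. The offset of 50 used for them shrinks the changes of dim genes. Of 187 genes taken by the naming rule, 49 had a value over 1.5 times as large, in the same direction, with the deposited values. Those differ in scaling as well as in the offset.

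The first comparison asks how colorectal cancer cells respond when glucose is removed and glutamine is left. In both lines, genes of the endoplasmic reticulum stress response and of the amino acid response driven by the transcription factor ATF4 were higher without glucose, and genes of mitosis and DNA replication were lower. The gene with the largest shared increase was DDIT3, which encodes the stress transcription factor CHOP, at 4.43 in DLD1 and 4.71 in HT29 (mean 4.57 ± 0.19, SD, n = 2 lines). HERPUD1, a component of endoplasmic reticulum-associated degradation, was 2.82 and 3.01 higher, and HSPA5, the main chaperone of that compartment, 1.95 and 2.25 higher. The mitotic kinesin gene KIF20A was lower by the largest shared amount, at -2.26 in DLD1 and -2.13 in HT29 (mean -2.20 ± 0.10, SD, n = 2 lines). The lactate dehydrogenase gene LDHA was also among the lowest, at -1.62 and -2.07.

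Of the 12 genes with the largest shared increase, DDIT3, HERPUD1, PDIA4, CRELD2, HSPA5, HSP90B1 and ERO1B belong to the stress response of the endoplasmic reticulum, and DDIT4 encodes an inhibitor of mTORC1. DDIT4 was 2.57 higher in DLD1 and 2.55 higher in HT29. LCN2, which encodes the iron-sequestering protein lipocalin 2, was 2.60 and 2.55 higher. LURAP1L was 2.49 and 3.46 higher, and the small nucleolar RNA host gene SNHG32 2.38 and 1.95 higher, although its mean change was -0.31 when the local background was subtracted. FTHL17 was 1.97 and 2.12 higher, as read by a probe whose target resembles other ferritin heavy chain genes, so its identity is uncertain. The 12 lowest genes were KIF20A, CCNB1, PSRC1, SAPCD2, AURKA, HMGN3, CCNA2, BIRC5, LDHA, CDCA3, DLGAP5 and CDKN3. Of these, CCNB1 and CCNA2 encode the mitotic cyclins B1 and A2. CCNB1 was -1.92 in DLD1 and -2.38 in HT29, and CCNA2 -1.69 and -2.54. AURKA, which encodes a spindle kinase, was -1.72 and -1.92, and BIRC5, which encodes survivin, -1.72 and -1.69.

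**Figure D1:**
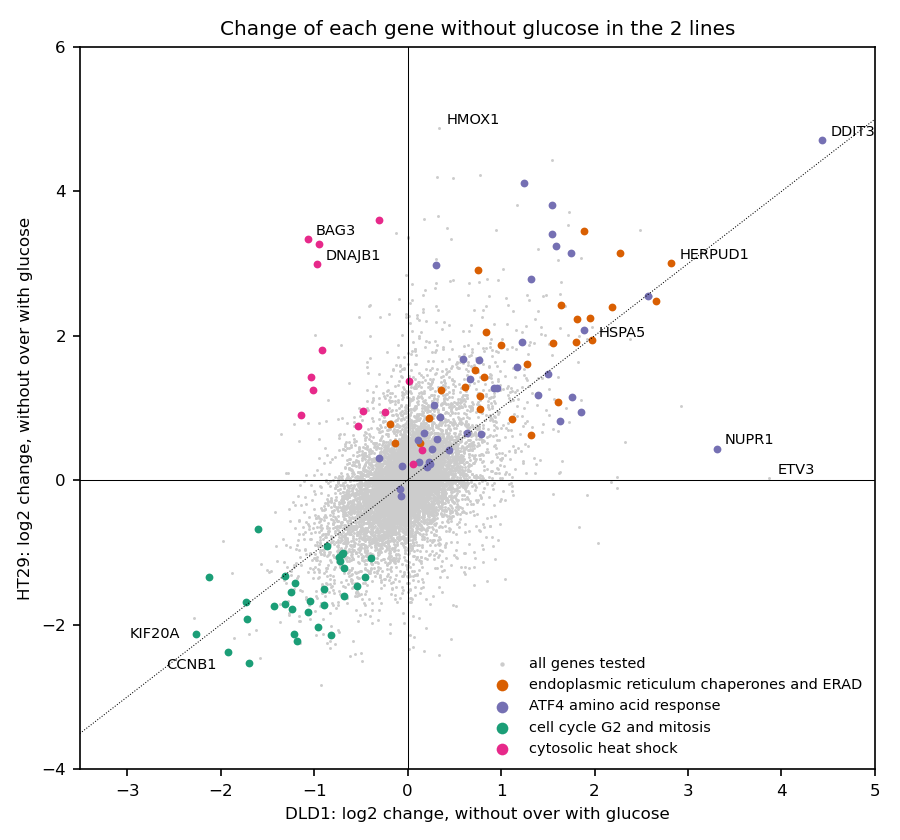
Log2 change of each of 15616 genes without over with glucose, in DLD1 (x axis) and HT29 (y axis), with the members of 4 gene lists in colour and a dotted line of equal change. Endoplasmic reticulum and ATF4 genes lie mostly at the upper right (DDIT3 at 4.43 and 4.71), mitotic genes at the lower left (KIF20A at -2.26 and -2.13), and most cytosolic heat shock genes at the upper left (BAG3 at -1.07 and 3.34).

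Of 28 measured genes for endoplasmic reticulum chaperones and degradation, 26 were higher without glucose in both lines, with a median of 1.20 in DLD1 and 1.74 in HT29. At least 2-fold increases were seen for 16 of them in DLD1 and 21 in HT29. PDIA4, a disulfide isomerase, was 2.66 and 2.49 higher, ERO1B, a disulfide oxidase, 2.27 and 3.14, and the co-chaperone DNAJB9 1.89 and 3.45. Of the 28, 15 had a limma adjusted p below 0.05 when adjusted over the list alone, all of them higher, against 0 over all genes tested. For this list, adjusted p = 0.815 in limma's camera with an estimated correlation, a form that rests on 1 residual degree of freedom and has little power to call any list.

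Of 40 genes of the ATF4 amino acid response, 36 were higher in both lines, with medians of 0.77 and 1.099. The eIF2α phosphatase subunit gene PPP1R15A was 1.25 higher in DLD1 and 4.12 in HT29, and ATF3 1.55 and 3.81. The transfer RNA synthetase genes WARS1 (1.89 and 2.07), CARS1 (1.40 and 1.18) and GARS (0.92 and 1.27) were higher by similar amounts in both lines. ATF5 and STC2 were the 2 members lower in both, at -0.07 and -0.22 for ATF5 and -0.08 and -0.13 for STC2. Of the 40, 11 had a limma adjusted p below 0.05 adjusted over the list alone, all higher, against 0 over all genes tested, and camera gave adjusted p = 0.815 with an estimated correlation. Of 11 genes for serine and one-carbon synthesis the medians were only 0.00 and 0.23. The HT29 median was -0.01 with median scaling and -0.15 with the local background subtracted, and the DLD1 median was 0.25 (percentile 98.3) with the deposited values. MTHFD2, the mitochondrial folate enzyme, was nevertheless 1.92 and 1.96 higher and SHMT2 0.90 and 1.25 higher, while TYMS, thymidylate synthase, was -0.57 and -2.40. MTHFD2, SHMT2 and PSAT1 had a limma adjusted p below 0.05 adjusted over the list alone (3 of 11, all higher).

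All 31 measured genes of G2 and mitosis were lower in both lines, with medians of -1.06 in DLD1 and -1.60 in HT29, and 17 were lower by at least 2-fold in DLD1 and 29 in HT29. Limma gave 22 of the 31 an adjusted p below 0.05 adjusted over the list alone, all lower, against 0 over all genes tested, and camera gave adjusted p = 0.815 with an estimated correlation. PTTG1, the securin gene, was -1.31 and -1.32, as read by a probe that related pseudogenes may share. Of 35 genes of DNA replication, 29 were lower in both lines, with medians of -0.51 and -1.29. Only 2 of these were lower by at least 2-fold in DLD1, MCM7 (-1.27) and FEN1 (-1.22), against 23 in HT29. The helicase subunit gene MCM6 was -0.93 in DLD1 and -2.83 in HT29, and the sliding clamp gene PCNA -0.83 and -2.32. The licensing factor gene CDC6 was 0.11 and 1.17 higher. None of the 35 had a limma adjusted p below 0.05 adjusted over the list alone, and camera gave adjusted p = 0.815 with an estimated correlation.

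Of 23 genes of glycolysis and glucose uptake, 15 were lower and 3 higher in both lines, with medians of -0.26 in DLD1 and -0.16 in HT29. LDHA, ENO1 (-1.20 and -1.14), TPI1 (-1.14 and -1.17) and PKM (-0.88 and -0.94) were lower, and SLC2A1, which encodes the glucose transporter GLUT1, was 0.51 higher in each line. These 5 genes had a limma adjusted p below 0.05 adjusted over the list alone, against 0 over all genes tested. The list median lay at percentile 0.26 of matched random lists in DLD1 and at percentile 13.8 in HT29. The DLD1 position did not hold under other scalings, with a median of -0.33 at percentile 4.97 with median scaling, -0.17 at 4.0 with cyclic loess and -0.36 at 4.72 with the deposited values, and was -0.065 at 21.9 with the local background subtracted. TXNIP, a glucose-induced gene, was -0.78 and -1.06, or -3.06 and -2.13 in the deposited values (37.6 to 4.5 in DLD1 and 100.1 to 22.8 in HT29), while the 7 genes of its MondoA and ChREBP list had medians of -0.04 and 0.12, the second 0.80 with the deposited values. Of 8 gluconeogenesis genes, with medians of 0.02 and -0.01 (the second 0.03 with median scaling), PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, was 1.85 and 0.95 higher. In the pentose phosphate list (6 genes, medians 0.04 and 0.07, both negative with median scaling and the first also with the deposited values), RPIA was -0.67 and -0.74 and PGLS 0.68 and 0.61, and these 2 had a limma adjusted p below 0.05 adjusted over the list alone.

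In all, 188 genes were at least 2-fold higher and 129 at least 2-fold lower in DLD1 without glucose, and 600 higher and 522 lower in HT29. Both lines shared 111 of the higher genes, against 7.18 for independent lists (188 × 596 / 15616), and 69 of the lower genes, against 4.15 (126 × 514 / 15616). The pairs share no array. Across genes, which are not independent replicates, the changes in the 2 lines had a Pearson correlation of 0.518 (Spearman 0.431, covariance 0.0945), and 63.7% of genes changed in the same direction. Limma with the line as a block called no gene for the mean effect of the medium at an adjusted p below 0.05 (smallest adjusted p = 0.302), with 2157 genes at an unadjusted p below 0.05, 947 of them higher, against 781 at a rate of 0.05. On simulated data the same fit gave 6.33% of unchanged genes such a p, so 781 is too low a count for chance. This fit has 1 residual degree of freedom, and on simulated data it called 0% of genes planted at 8-fold. The 2-fold count in both lines found 98% of them and 44 unchanged genes, higher and lower together. The 44 exceed the 7.18 and 4.15 of independent lists, which are therefore also too low as counts for chance. Median scaling in place of quantile normalization moved the split of higher and lower genes to 96 and 324 in DLD1, 448 and 905 in HT29, and 60 and 190 in both.

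The gene lists fixed before the data were examined were then compared by their medians. Of 35 lists with at least 5 measured genes, 6 lay above the central 95% of matched random lists in both lines: the ATF4 and endoplasmic reticulum lists, hypoxia response (medians 0.35 and 0.44), NRF2 targets (0.32 and 0.77), immediate early genes (0.31 and 0.52), and NF-kB and chemokine genes (0.06 and 0.20). The mitosis and DNA replication lists lay below it in both lines. With the local background subtracted, 4 of the 6 stayed above it, since in DLD1 the immediate early genes (percentile 96.1) and the NF-kB and chemokine genes (percentile 90.7) fell inside. With the deposited values the medians were larger, at 0.43 and 1.96 for immediate early genes, 0.24 and 0.72 for NF-kB and chemokine genes, and 0.41 and 0.92 for hypoxia response. Other settings gave smaller ones. Hypoxia response was at 0.16 and 0.24 with the local background subtracted. In DLD1, immediate early genes and NRF2 targets were each at 0.13 with median scaling. Camera with a preset correlation of 0.01 gave 14 lists a limma adjusted p below 0.05, and 0 with an estimated correlation, where the smallest adjusted p was 0.815. The estimated form rests on 1 residual degree of freedom, so the absence of calls says little about the lists. Of 19 hypoxia response genes, 13 were higher in both lines, with NDRG1 at 0.77 and 4.23 and ADM, which encodes adrenomedullin, at 0.66 and 2.73. Among 22 NRF2 targets, 17 were higher in both lines, and TXNRD1, thioredoxin reductase, was 1.51 and 1.89 higher. Of 23 immediate early genes, 17 were higher in both, with CCN1 at 1.68 and 2.42, CCN2 at 1.13 and 2.35, and KLF6 at 0.96 in each line (limma adjusted p = 0.040, adjusted over the list alone). In the NF-kB and chemokine list, where 12 of 21 genes were higher in both lines, LCN2 was the member with the largest mean change and had a limma adjusted p of 0.0052 adjusted over the list alone, while NFKBIA was 0.46 and -1.17. Over all genes tested, no limma adjusted p for the medium was below 0.302.

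**Figure D2:**
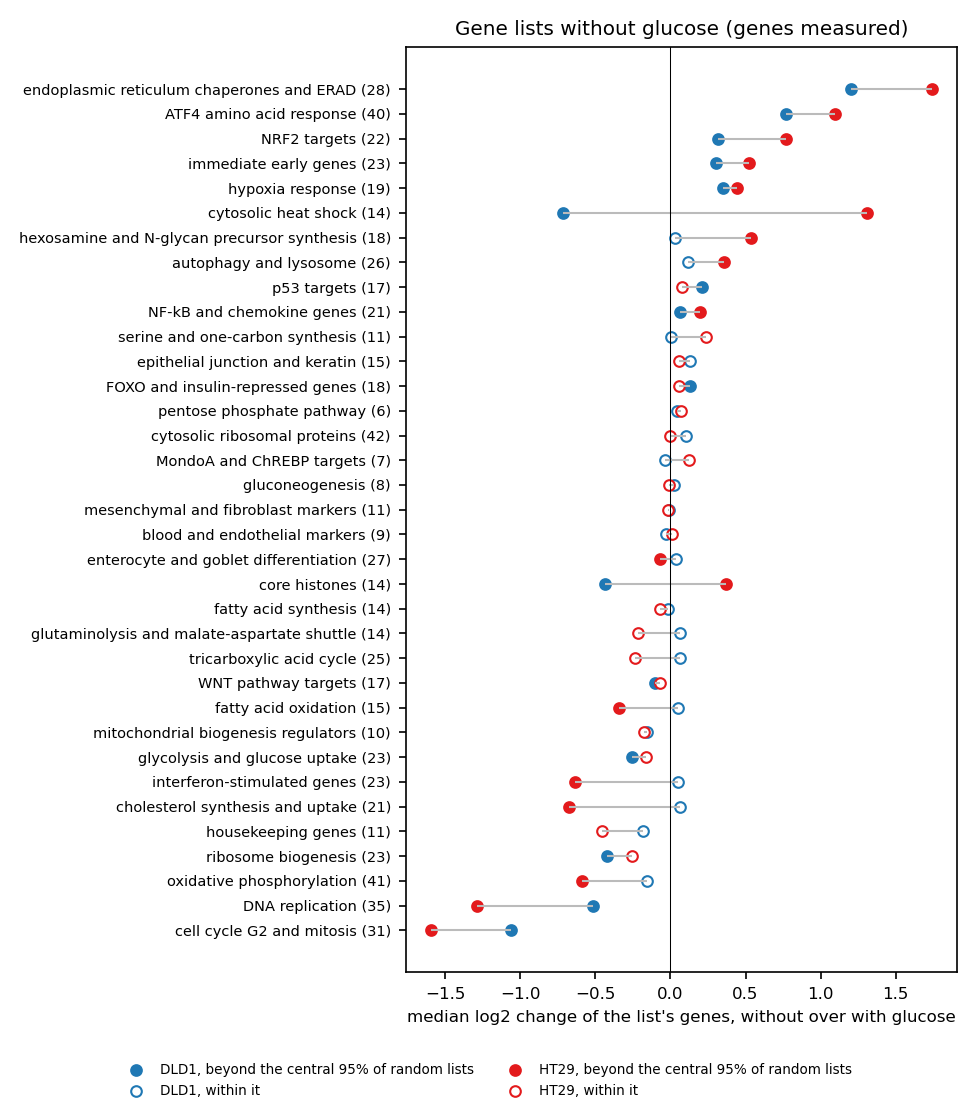
Median log2 change without over with glucose (x axis) of 35 gene lists (y axis, with the number of genes measured) in DLD1 and HT29, filled where the median lay outside the central 95% of 10000 random lists matched on expression. Cytosolic heat shock genes (-0.72 and 1.31) and core histones (-0.43 and 0.37) lie on opposite sides of 0 in the 2 lines.

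Genes of oxidative phosphorylation lay below the central 95% of random lists in HT29 and within it in DLD1, a difference between lines that was not tested. Of 41 measured, 32 were lower and 0 higher in both lines, with medians of -0.16 in DLD1 (percentile 7.12) and -0.59 in HT29 (percentile 0.010). With the local background subtracted the medians were 0.02 and -0.24, the latter at percentile 3.63 and no longer below the limit. With median scaling they were -0.50 (percentile 2.47) and -0.77, below it in both lines, and the DLD1 median was -0.43 (percentile 3.72) with the deposited values. The ATP synthase subunit genes ATP5MC3 (-1.15 and -1.53) and ATP5MC1 (-1.04 and -1.02) were lowest. No gene of the list had a limma adjusted p below 0.05 adjusted over the list alone, and camera gave adjusted p = 0.815 with an estimated correlation. Among 10 regulators of mitochondrial biogenesis (medians -0.16 and -0.18), TFAM, the mitochondrial transcription factor, was -0.83 and -0.89 and POLRMT, the mitochondrial RNA polymerase, -0.50 and -0.45, each with a limma adjusted p below 0.05 adjusted over the list alone. The DLD1 median of these regulators lay at percentile 2.64. With the deposited values their medians were -0.53 (percentile 0.68) and -0.33 (percentile 15.1). The 25 genes of the tricarboxylic acid cycle had medians of 0.06 and -0.24, the first of which was -0.16 with median scaling and -0.10 with the deposited values. SUCLG1 was -0.74 and -1.08, and ME1, the cytosolic malic enzyme, 0.37 and 1.84. Ribosome biogenesis genes had medians of -0.42 (percentile 0.020) and -0.25 (percentile 10.8), with 16 of 23 lower in both lines, led by BOP1 (-0.78 and -0.74), whereas the 42 cytosolic ribosomal protein genes had medians of 0.10 and -0.01, the second above 0 with median scaling, cyclic loess and the deposited values, under each of which the list lay above the central 95% in both lines.

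The genes at least 2-fold higher in DLD1 with a change under 0.5, or of opposite sign, in HT29 were led by ETV3, an ETS-family repressor gene, at 3.87 in DLD1 and 0.04 in HT29. NUPR1, a stress-induced nuclear protein gene, was 3.31 higher in DLD1 and 0.44 in HT29, with deposited intensities of 24.4 and 515.5 in DLD1 and 9.0 and 27.8 in HT29. The deposited values of this dim gene in HT29 thus gave a change of 1.63, so its small change there depends on the processing. The receptor gene CMKLR2 was 2.24 higher in DLD1 and -0.10 in HT29, a difference that ended with the local background subtracted (0.055, HT29 minus DLD1). HCFC1R1 (2.24 and 0.05) and the placental alkaline phosphatase gene ALPP (2.18 and -0.02) followed, and ALPP has close relatives that its probe may also read. The genes lower in DLD1 by the same rule were TUBA4A (-1.42 and -0.43), HSP90AA2P (-1.35 and 0.65), the chaperonin subunit gene TCP1 (-1.30 and 0.10), EWSR1 (-1.28 and 0.10) and HNRNPU (-1.27 and -0.39). The HSP90AA2P probe may read HSP90AA1, its parent gene. These differences between lines rest on 1 array each and were not tested.

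HT29 responded to the same medium with larger changes, the SD over genes being 0.534 against 0.342 in DLD1, a ratio of 1.56 that was 0.917 with the local background subtracted. HMOX1, heme oxygenase 1, was 4.88 higher in HT29 and 0.33 in DLD1, with deposited intensities of 164.7 and 7273 in HT29. The phosphatase gene DUSP1 was 4.20 higher in HT29 against 0.32 in DLD1, the cell cycle inhibitor gene CDKN1A 4.18 against 0.49, and GADD45B 3.65 against 0.33. The inducible chaperone gene HSPA6 was 3.62 higher in HT29 against 0.18 in DLD1, or 9.25 against 1.02 in the deposited values. Genes at least 2-fold lower in HT29 with a change under 0.5, or of opposite sign, in DLD1 were DUT, which encodes dUTPase (-2.50 against -0.48), ACAT2 of sterol synthesis (-2.42 against 0.33), the tetraspanin gene TSPAN8 (-2.36 against 0.17), KRT13 (-2.34 against 0.02) and BMP4 (-2.30 against 0.06). KRT13 was dim in DLD1 (deposited 9.8 with and 11.2 without glucose), so it had little room to fall there. As in DLD1, these differences between lines were not tested.

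Of the 35 lists, that of the cytosolic heat shock genes had the medians furthest apart in the 2 lines, with 1 culture per line and medium. Of 14 measured, 11 were lower in DLD1 and higher in HT29, and the list median was -0.72 in DLD1 and 1.31 in HT29. With the local background subtracted the DLD1 median was -0.21, at percentile 16.3 and inside the random lists. On the DLD1 array without glucose, Positive Control 2 spots had a median signal of 7180, against 14109 on the DLD1 array with glucose, and relative to these spots the list median in DLD1 was 0.031. BAG3, a co-chaperone gene, was -1.07 and 3.34, DNAJB1 -0.97 and 2.99, HSPH1 -0.91 and 1.80, and HSPA1B -0.95 and 3.27. HSPA1A and HSPA1B are near-identical, so their values are uncertain as single genes. As normalized here, 4 genes were changed at least 2-fold in opposite directions. The count was 2 with cyclic loess, 9 with median scaling, 15 with an offset of 5, 40 with the local background subtracted and 69 with the deposited values. Of these 69, 7 were of the heat shock list. The 4 were BAG3, DNAJA1 (-1.03 and 1.43), HSPA4L (-1.01 and 1.25) and, chosen after its values were seen, IAH1 (1.05 and -1.36). Interferon-stimulated genes had a median of 0.05 in DLD1 (percentile 87.2) and -0.64 in HT29 (percentile 0 of the random lists, -0.33 with the local background subtracted and -1.49 with the deposited values), with OAS3 at -0.50 and -2.39 and IFIT1 at -0.28 and -1.70, while ISG20 was 1.48 and 2.57 higher. Between the lines, the interferon list was higher in HT29 by a median of 0.63 with glucose and 0.015 without. Genes of cholesterol synthesis and uptake had medians of 0.06 in DLD1, which was -0.24 with median scaling and -0.14 with the deposited values, and -0.68 in HT29, with the mevalonate kinase gene MVK at -0.80 and -1.73. Changes at least 4-fold apart were found for 67 genes with HT29 above DLD1 and 24 with HT29 below. No residual degrees of freedom remain for the interaction, so it was not tested.

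**Figure D3:**
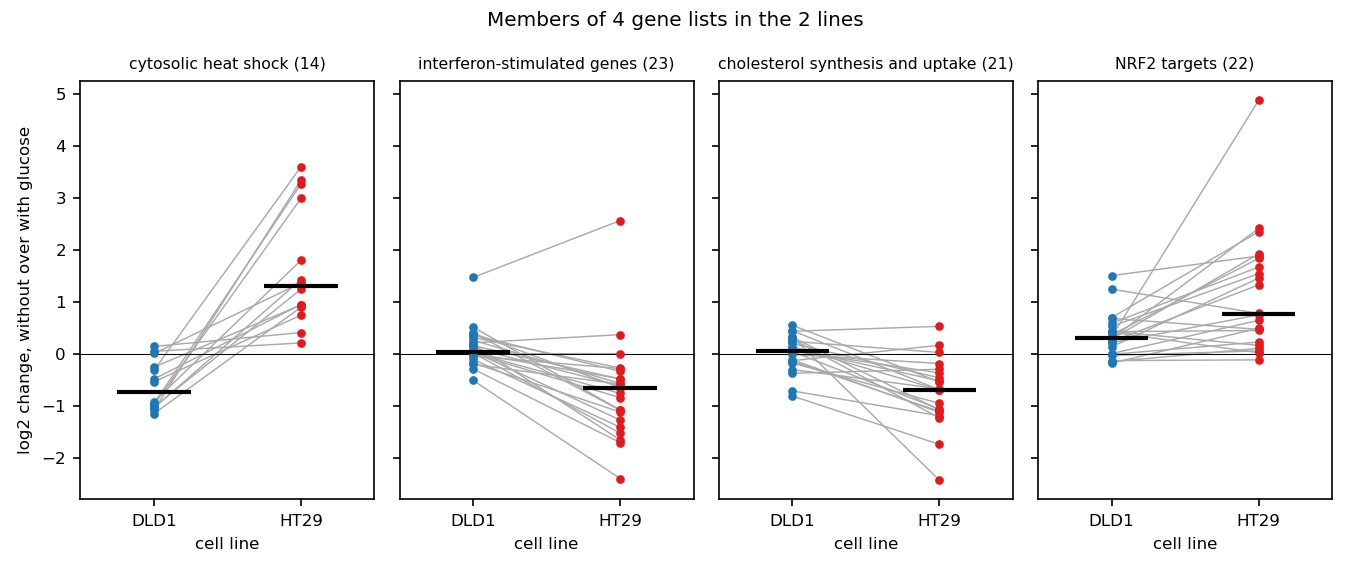
Log2 change without over with glucose (y axis) of each member of 4 gene lists in DLD1 and HT29 (x axis), with a grey line joining the values of a gene and a black bar at the list median. Heat shock genes run from -0.72 to 1.31 in the median, interferon-stimulated genes from 0.05 to -0.64, cholesterol genes from 0.06 to -0.68, and NRF2 targets from 0.32 to 0.77.

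The lines also differed from each other in both media, as the design allows to be compared. LYZ, the lysozyme gene, was 8.27 higher in HT29 than in DLD1 with glucose and 6.76 higher without. The intestinal genes GCNT3 (5.77 and 5.80), GPX2 (7.13 and 5.50) and LGALS4 (5.31 and 5.84) were also higher in HT29, as were IFI27 (6.81 and 4.97), BST2 (6.15 and 4.50), HSPA1A (4.81 and 8.72) and TM4SF4 (6.95 with glucose). HSPA1A is near-identical to HSPA1B, and had deposited intensities of 21.4 in DLD1 and 2044 in HT29 with glucose. Those of HSPA1B were 528.4 and 1544.5, so the line difference of HSPA1A as a single gene is uncertain. In DLD1 without glucose TM4SF4 was not above background, so that it was at least 31.8-fold higher in HT29 there. Lower in HT29 were the chemokine gene CXCL5 (-6.35 and -5.79), TNNC1 (-5.41 and -5.99), GSTM3 (-4.97 and -5.16), EPDR1 (-3.99 and -4.19), CD99 (-4.43 and -3.96), GDPD3 (-3.90 and -4.40) and OLR1 (-4.82 and -4.83, but 0.28 on average with the local background subtracted). In both media 277 genes were at least 2-fold higher in HT29 and 297 lower, or 381 and 226 with median scaling. Limma with the medium as a block called 0 genes (smallest adjusted p = 0.136, 3343 genes at an unadjusted p below 0.05), but 324 higher and 329 lower with the deposited values and 84 and 116 with an offset of 5 in place of 50.

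The last comparison concerns glutamine metabolism, the fuel left in the medium. From general knowledge of the study, GLUD1 and SLC25A13 were followed up in it and may have been chosen on these arrays, so they are not independent evidence. GLUD1, glutamate dehydrogenase, was 0.51 higher in DLD1 and -0.41 in HT29, with deposited intensities of 339.5 with and 420.0 without glucose in DLD1, and 529.5 and 370.8 in HT29. SLC25A13, a mitochondrial aspartate-glutamate carrier, was -0.57 in DLD1 and -0.63 in HT29 (deposited 205.0 and 117.5, then 259.8 and 141.5). Its limma adjusted p was 0.039 adjusted over the glutamine list alone and 0.302 over all genes. Of 14 genes of glutaminolysis and the malate-aspartate shuttle, 4 were higher and 5 lower in both lines, with medians of 0.06 (-0.04 with median scaling and -0.05 with the deposited values) and -0.22. ASNS, asparagine synthetase, was 1.23 and 1.91 higher and GOT1, the cytosolic aspartate aminotransferase, 0.59 and 2.07 higher. The second aspartate-glutamate carrier gene SLC25A12 was -0.80 and -0.79 (-2.41 and -3.05 in the deposited values, 45.6 to 8.6 and 41.4 to 5.0), with limma adjusted p = 0.037 adjusted over the list alone, and GOT2, the mitochondrial aminotransferase, was -0.51 and -0.74. GLUD1 and SLC25A13 have 1 probe each, and the change of GLUD1 was 0.17 in DLD1 and -0.70 in HT29 with median scaling.

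**Figure D4:**
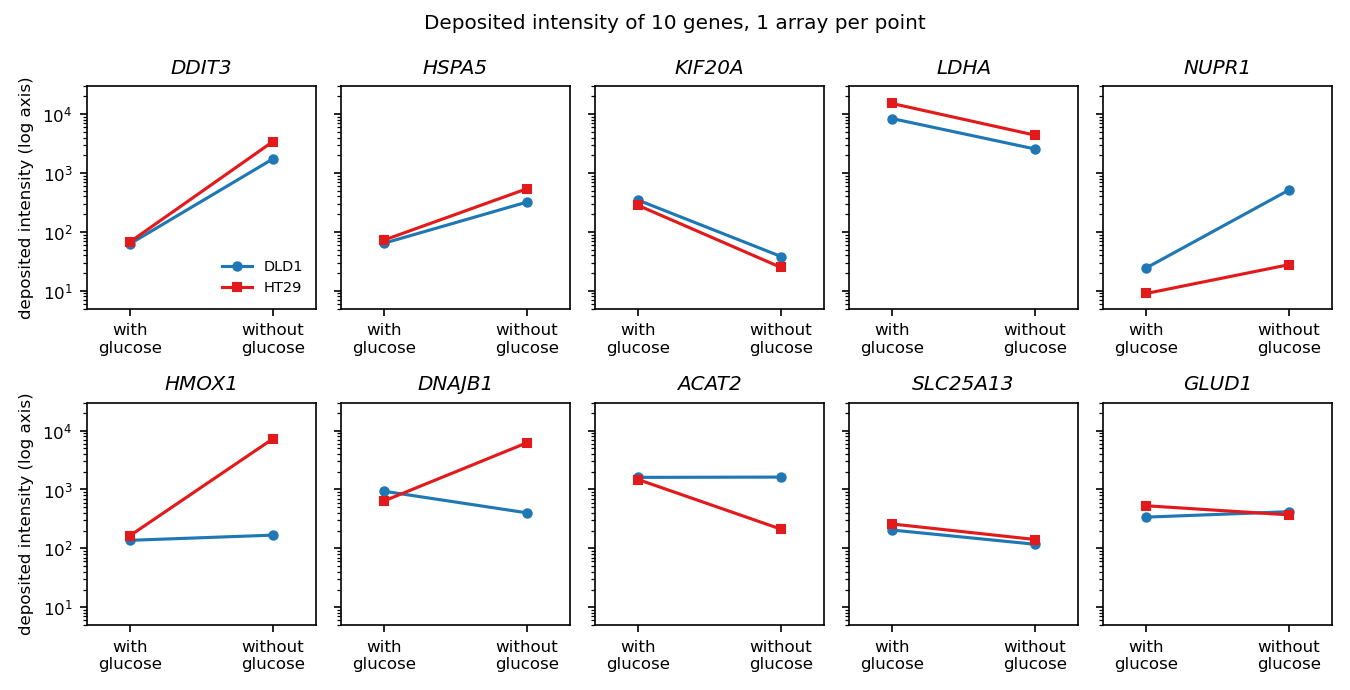
Deposited intensity (y axis, log scale, each array scaled to a median of 25) of 10 genes with and without glucose (x axis), 1 array per point, with lines joining the 2 arrays of DLD1 and of HT29. DDIT3 runs from 62.8 to 1736 in DLD1 and from 67.6 to 3421 in HT29, whereas HMOX1 reaches 167.9 in DLD1 and 7273 in HT29 without glucose.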

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

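The tests of measurement noise, those of scaling and of an array-wide factor for the heat shock and interferon genes, and that of the cultures with glucose for the interferon genes were chosen after results were seen. The others were written down before their tests, but for patterns already seen in these data. For the background correction, it was already known that subtracting the local background ended the pattern.

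Cytosolic heat shock genes had list medians of opposite sign, -0.719 in DLD1 and 1.31 in HT29, and BAG3 with -1.07 and 3.34, a difference that was not tested. Over 3 other scalings the list stayed at percentile 0.010 or lower in DLD1 and above the upper limit in HT29. The choice of scaling therefore does not account for its place among other genes. An array-wide factor moves the random lists too, so these percentiles cannot speak to one. The sign in DLD1 stays open to such a factor, since the list median there was 0.031 relative to the Positive Control 2 spots and -0.82 relative to the Positive Control 1 spots. With the local background subtracted the DLD1 median was -0.21, at percentile 16.3, so the DLD1 side no longer stood apart, while HT29 was at 1.04. A difference that lay only in the cultures with glucose was not seen on these arrays: HT29 minus DLD1 had a median of 2.43 without glucose (95% bootstrap interval over genes 0.980 to 3.43) against 0.04 with it (-0.41 to 0.84). The intervals resample genes that change together and do not measure the spread between cultures. A difference in temperature or handling of a single culture cannot be told apart from the line, because the difference of 2.03 between the list medians comes from 1 culture per line and medium, and the line itself also stays open.

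The changes in HT29 were larger than in DLD1, with a ratio of SDs of 1.56. Noise alone is argued against, since the covariance between 2 probes of a gene, to which independent spot noise adds nothing, was 2.61 times as large in HT29 (95% interval 2.24 to 3.06 over 1742 genes). The lowest ratio of SDs over 3 other scalings was 1.54. A constant factor per array leaves an SD of log2 changes as it is, so these ratios only ask whether the quantile step made the pattern. Subtracting the local background ended the pattern (0.917), but it lowered the correlation between probes of a gene from 0.708 to 0.188 in DLD1 and from 0.738 to 0.557 in HT29, which is the reverse of what a better background estimate would give. Whether the ratio of 1.56 belongs to the line or to these single cultures cannot be told apart with 1 array each, and both stay open.

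Interferon-stimulated genes were lower in HT29 (list median -0.64) and not in DLD1 (0.05), a difference that was not tested. Levels too dim to fall do not account for the DLD1 value, since 13 members with a deposited intensity of at least 25 in DLD1 had a median of 0.12 there, while 11 of them were lower in HT29. HT29 stayed at percentile 0 over 3 other scalings, so the choice of scaling does not account for the place of the list. An array-wide factor moves the random lists too, so percentiles cannot speak to one. Relative to the Positive Control 1 and 2 spots, the HT29 medians were -0.52 and -0.98 and the DLD1 medians 0.13 and 0.99. Scaling to either kind of spot thus left the list lower in HT29 and not in DLD1, and the prediction for such a factor was not met. The files do not say what these spots measure, and the kinds give different factors. The values therefore speak only to a factor that these spots follow, and any other stays open. The HT29 median was -0.33 with the local background subtracted. On the arrays with glucose the list was higher in HT29 by a median of 0.63 (95% bootstrap interval over genes 0.36 to 1.13), against 0.015 without glucose (-0.43 to 0.45). These intervals resample genes that change together (camera's estimated correlation 0.53) and do not measure the spread between cultures. The values with and without glucose met the prediction, made after results were seen, for cultures that differ with glucose and not without. A higher starting level in the HT29 culture with glucose therefore stays open. That the lines differ in this response may be a property of the lines, as a hypothesis, but with 1 pair of arrays per line the value of -0.64 cannot be told apart from that of a single culture.

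Core histone genes had list medians of -0.434 in DLD1 and 0.373 in HT29, a difference that was not tested and whose DLD1 side was -0.05, at percentile 17.4, with the local background subtracted, and histone probes may read several near-identical genes. HT29 minus DLD1 had a median of -0.51 for them with glucose (-1.28 to -0.11, over genes and not over cultures) and 0.056 without (-0.035 to 0.27). Relative to Positive Control 2 spots their medians had the same sign, 0.31 in DLD1 and 0.15 in HT29, and relative to Positive Control 1 spots opposite signs, -0.54 and 0.61. Among the probes without a gene symbol, which no comparison used, 9 were at least 2-fold higher and 6 at least 2-fold lower in both lines, out of 3447 above background in both, and their changes had r = 0.533 between the lines.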

How the results depend on the processing

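The offset of 5 and the local background were chosen after seeing the data. The directions of the 6 shared higher and 2 shared lower lists held in both lines under all alternatives that recomputed the lists. Scaling to the positive control spots was not among these, as it was computed for 3 other lists only. Relative to Positive Control 2 spots the median change of all genes in DLD1 was 0.94. The signs of the shared lists in DLD1 were not tested against such a factor. Genes at 2-fold numbered, in DLD1 higher and lower, 737 and 777 with the deposited values, 398 and 334 with an offset of 5, 503 and 562 with the local background, and 96 and 324 with median scaling. In HT29 they were 1662 and 1796, 1044 and 1119, 492 and 423, and 448 and 905 in the same order, so the local background raised the DLD1 counts and lowered those of HT29. The cause was not tested. Genes changed in both lines numbered 294 and 328, 214 and 164, 131 lower with the local background, and 60 and 190 with median scaling, which shared 60 and 69 genes with the 111 and 69 reported, against 60 and 34 shared with the local background. A 1.5-fold minimum gave 648 and 719 in DLD1, 1240 and 1409 in HT29 and 359 and 405 in both, and a 3-fold minimum 53 and 13, 216 and 116, and 31 and 9. Changes 4-fold apart, HT29 above and below DLD1, numbered 322 and 269 with the deposited values, 154 and 97 with an offset of 5 and 133 and 90 with the local background. Genes 2-fold higher and lower in HT29 in both media were 1061 and 854, 585 and 691, and 183 and 193 in the same order. The limma count for the line was 324 and 329 with the deposited values, 84 and 116 with an offset of 5, 10 and 15 with no block, and 0 otherwise. For the medium limma called 0 genes in every fit, with the block or without it. The correlation between the lines was 0.405 with the deposited values, 0.560 with median scaling, 0.475 with an offset of 5 and 0.354 with the local background. Lists higher in both lines were 10 with the deposited values, adding p53 targets, autophagy, FOXO and ribosomal protein genes, and 4 with the local background, where immediate early and NF-kB genes no longer stood apart in DLD1, and lists lower in both 4 with median scaling, adding oxidative phosphorylation and WNT targets. Of 32 list medians outside the random lists in a line, 10 no longer were with the local background.

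Leaving out a line left no residual degrees of freedom, so limma gave no value. The other line alone had 188 to 596 genes higher, 126 to 514 lower, 8 to 10 lists higher and 7 lower. With a medium left out, 477 to 741 genes were higher and 426 to 747 lower in HT29. GLUD1 was 0.17 in DLD1 and -0.70 in HT29 with median scaling, 0.31 in DLD1 with the deposited values, and 0.066 and -0.24 with the local background. GLUD1 and SLC25A13 have 1 probe each, so reading probes singly changed nothing.

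Values of the named genes and of 11 lists were compared 1298 times: 981 times they moved little, 307 times by more, and 10 times, all for genes, the sign reversed of a change shared by both lines or of a line difference. Limma called no gene at all for the medium, so the absence of a call does not set these genes apart. SNHG32, among the genes with the largest shared increase, was one of them. Over all 35 lists, the median of a list in a line changed sign in 32 of 560 comparisons. Only 1 of these had lain outside the random lists, fatty acid oxidation in HT29 (0.018 with the local background). GPT2 reversed with median scaling (-0.037). With the local background the mean changes of SNHG32 (-0.31), IDH1 (-0.23), TFB2M (0.038), FDPS (0.27), CTSL (-0.19), FN1 (0.028) and MDH2 (2.76), the line differences of CMKLR2 (0.055) and OLR1 (0.28), and the ratio of SDs (0.917) reversed. The cause was not tested beyond the lower correlation between probes (0.188 in DLD1 and 0.557 in HT29). Camera with an estimated correlation ended all 14 calls. Signal over background limits dim genes: blank spots had an SD of 1.28 to 1.92 around 34.4 to 35.6, against median probe signals of 53.1 to 57.9.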

Other observations

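Of 4 further gene groups, none stood apart from the random lists in both lines as normalized here, but autophagy genes and p53 targets lay above them in both with median scaling and the deposited values, p53 targets also with an offset of 5, and FOXO genes with the deposited values. Camera with an estimated correlation gave limma adjusted p = 0.815 or higher for each, and each held at least 1 gene that was 2-fold or more higher in both lines. Autophagy and lysosome genes had medians of 0.12 in DLD1 (percentile 95.6) and 0.36 in HT29 (beyond the upper limit), with 15 of 26 higher in both lines. WIPI1, a protein of early autophagosomes, was 1.86 and 3.07 higher, GABARAPL1 1.39 and 3.20, MAP1LC3B, which encodes LC3B, 0.95 and 3.47, and the autophagy receptor gene SQSTM1 1.06 and 2.16. Genes of hexosamine and N-glycan precursor synthesis had medians of 0.03 (percentile 70.4, -0.11 with median scaling and -0.03 with the deposited values) and 0.54, and GFPT1, the first enzyme of the hexosamine route, was 1.45 and 2.55 higher, PGM3 0.45 and 2.15, and GMPPB 0.81 and 1.79. The p53 target list had medians of 0.21 and 0.08 (percentile 84.0), with GADD45A 1.28 and 2.57 higher, GDF15 1.26 and 2.14, and PMAIP1 0.87 and 2.54. FOXO and insulin-repressed genes had medians of 0.13 and 0.06 (percentile 89.0), led by FBXO32 (0.42 and 3.49) and KLHL24 (1.14 and 1.22). KLHL24 had a limma adjusted p of 0.027 adjusted over the list alone, whereas none was below 0.302 over all genes.

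Fatty acid synthesis genes had medians of -0.02 and -0.07, the second -0.66 (percentile 0.29) with the deposited values and -0.36 (percentile 0.43) with an offset of 5, with FASN, fatty acid synthase, at -1.05 and -1.92. Fatty acid oxidation had medians of 0.05 and -0.35 (0.018 in HT29 with the local background subtracted), with HADH at -0.55 and -1.57 and CPT2 at -0.10 and -1.10. WNT pathway targets had medians of -0.11 and -0.07, with SP5 at -0.64 and -0.70 and SOX9 at 0.06 and -1.32.

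Enterocyte and goblet genes had medians of 0.04 and -0.07, or 0.22 and -0.29 with the deposited values. The HT29 position, at percentile 2.44, ended under 5 alternatives, at 3.63 to 19.3. AGR2, a disulfide isomerase of goblet cells that is also a stress gene of the endoplasmic reticulum, was 1.17 and 3.81 higher. Epithelial junction and keratin genes had medians of 0.13 and 0.05 (-0.02 and -0.24 with median scaling), with ESRP1 1.57 and 1.13 higher. Mesenchymal markers had medians of -0.01 and -0.01 (the second 0.06 with median scaling), and blood and endothelial markers -0.03 and 0.01, or -0.43 (percentile 1.67) and 0.18 with the deposited values. LYZ, a member of the latter list, was bright in HT29 (deposited 15522 with glucose), while CD14 and KDR were at 38.4 and 24.3 there, although levels of different probes are not on a common scale. The 11 housekeeping genes had medians of -0.18 and -0.46, below 0 under each scaling. ACTB was -0.97 in DLD1 and 0.14 in HT29.

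Positive Control 2 spots had a median signal of 7180 in DLD1 without glucose, against 14109 in DLD1 with glucose and 12247 and 12064 in HT29. Positive Control 1 spots were at 36028 and 39106 in DLD1 without and with glucose, and at 29151 and 40742 in HT29. The files do not say what these spots measure. Every change within DLD1 rests on this array, the lower heat shock genes included, and its sign assumes that most genes stayed level. Relative to Positive Control 2 spots the median change of all genes was 0.94 in DLD1 and -0.06 in HT29, and relative to Positive Control 1 spots 0.09 and 0.40, so the 2 kinds of control spot give different factors in each line.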
